A study of Caenorhabditis elegans with 2 samples.

How the data were processed

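Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole early embryos of a Caenorhabditis elegans strain that carries a transgene for HMBX-1 fused to GFP and FLAG at its C terminus, in an unc-119 mutant background. Per the labels, the embryos were taken 45 min after synchronization by bleaching and the sample description states that the immunoprecipitation used an antibody against GFP. The antibody field of the same labels names hmbx-1 instead; the text follows the description, and the labels do not settle the difference. The 2 samples are biological replicates of 1 group, so no contrast between conditions was made. No untagged or mock immunoprecipitation was analysed here, and p-values below compare sets of genomic regions, not conditions.

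The deposited files are region lists in the narrowPeak format. Per the file headers and accompanying notes, relaxed lists that hold peaks together with background regions were called for each replicate and for the pooled replicates, each against a control file that both replicates share, and a thresholded list was then made from these lists by the irreproducible discovery rate (IDR) procedure. The signal value per region is the authors' own peak-caller value as deposited; it was used only to rank and describe regions within a list and is not a read count. The deposited −log10 q value per region reached a shared maximum of 2.24 in the thresholded list and was used only for description. The aligner, the peak caller, their versions, the treatment of reads that map to several places and the IDR threshold are not given in the sources used here. Read depth is therefore unknown, and binomial intervals cover only the counting of regions. The pooled relaxed lists hold exactly 30000 regions in both assemblies.

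Lists exist for assemblies ce10 and ce11. All positions given are on ce11, 1-based; the ce11 chromosome lengths equal those of the WBcel235 reference used for sequence, and gene models came from the Ensembl annotation of that assembly. Amino acids of tRNA genes came from the RefSeq annotation, matched by gene identifier for 607 of 612 nuclear tRNA genes. No coordinate was converted between assemblies, and the ce10 lists entered only counts and the replicate overlap.

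Tests were run on the 416 thresholded regions of the 6 nuclear chromosomes, called peaks below. Another 21 thresholded regions lie on the mitochondrial genome and were kept out of the nuclear comparisons, a choice made when the lists were read. Sub-threshold regions are the 29307 nuclear regions of the pooled relaxed list that overlap no peak. The summit offset of each region was taken as its position. A protein-coding start is the 5' end of the gene model, and a peak within 500 bp of one was counted as promoter-proximal. A divergent promoter lies between head-to-head starts less than 2000 bp apart. A small RNA gene is an annotated tRNA, snoRNA, snRNA or rRNA gene, counted when the summit lies within 250 bp of it. Shares for promoters and small RNA genes were compared with 10000 random placements on the same chromosome, with a two-sided empirical p whose smallest possible value is 0.0002. Shares on the X, in the central 33.3% of the autosomes and within 50 kb of chromosome ends were compared with the share of sequence by two-sided exact binomial tests. Intervals are 95% exact Clopper-Pearson intervals, and a share of 0 carries the limit that 3 counts would give.

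Divergent promoters and telomere repeats were compared with sub-threshold regions by two-sided Fisher's exact tests. Repeats were searched as TTAGGCTTAGGC or its reverse complement within 100 bp of the summit. The TAGTTA word and all 2080 canonical 6-mers were searched within 50 bp of the summit and compared with up to 10 sub-threshold regions per peak, matched on GC decile and promoter class; 4074 matched regions were found. The 25 gene lists were tested by Fisher's exact test against the 6441 protein-coding genes with any pooled relaxed region within 500 bp of a start. Benjamini-Hochberg adjustment was made over the 2080 words, over the 25 lists, and over the 8 single location and motif tests, with a threshold of 0.05. Replicates were compared by the overlap of their regions of highest signal, with 10000 random draws as background, and by correlation of signal across peaks with 100000 permutations. For the hmbx-1 locus, relaxed regions in a 40 kb window were ranked among all such windows.

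The tests of the main results, most alternatives, the gene lists and the rule for naming genes were fixed before the data were examined; the alternatives and tests added later are named below and in the closing section. The rule names the genes with a start within 1000 bp of the 25 thresholded regions of highest signal, hmbx-1, unc-119, and up to 4 genes per list with the highest peak signal; of the 25 regions, 15 were mitochondrial and 3 of the 10 nuclear ones had such a gene. Peaks at named RNA genes, the split of peaks by distance to small RNA genes, and the tests on noncoding classes other than the 4 together, amino acids, summit positions, exons and differences between the classes of peak, were chosen after the values were seen. Alternatives covered each replicate alone, a stricter peak set, the pooled relaxed list, distances, windows and backgrounds. All 416 peaks were also the 416 nuclear regions of highest signal in the pooled relaxed list, so that alternative changes nothing and is left out of counts of alternatives.

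The procedures were tested on simulated data. The placement test for the promoter share gave a p under 0.05 in 3 of 100 sets of 416 random positions. The 6-mer screen called no word in any of 10 draws of sub-threshold regions, and recovered a planted word in 10 of 10 draws over 2080 words. Sub-threshold windows had a mean GC content of 34.6%, against 46.7% in peak windows. False calls from GC differences left after matching by decile were therefore not tested. The list test called any list in 6 of 100 draws of random genes, and called a list with 12 planted members in 100 of 100 draws, on 6441 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.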

Results

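HMBX-1 is the C. elegans relative of the human homeobox protein HMBOX1, also called HOT1, which binds telomeric repeats. Its occupancy was profiled by ChIP-seq of the GFP-tagged protein in early embryos, in 2 biological replicates. The thresholded list held 437 regions, of which 416 were nuclear and 21 mitochondrial. The relaxed lists held 25401 regions in replicate 1, 22915 in replicate 2 and 30000 for the pooled replicates. Nuclear peaks had a median width of 490 bp and signal values from 95.3 to 688.3, with a median of 134.0. The number of reads behind a region is unknown.

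The first question was where the peaks lay. Nearly as many peaks lay at genes for small structural RNAs as lay elsewhere. Of 416 nuclear peaks, 201 (48.3%, 95% interval 43.4 to 53.2) had their summit within 250 bp of a tRNA, snoRNA, snRNA or rRNA gene, against 0.652% ± 0.394 (SD over 10000 placements) for random positions. This was a 74.1-fold excess (permutation of positions, two-sided p = 0.0002, the smallest the placements can give; adjusted p = 0.000533). The same share was 46.6% among the 416 regions of highest signal in replicate 1 and 46.6% in replicate 2.

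Genes for tRNAs accounted for most of these peaks. There were 138 peaks at tRNA genes (33.2%, interval 28.7 to 37.9), where random placement gave 1.46 peaks. Another 51 peaks (12.26%, interval 9.27 to 15.8) lay at genes for snoRNAs, which guide RNA modification, and 13 (3.12%, interval 1.67 to 5.28) at snRNA genes. Each of these 3 classes reached a permutation p of 0.0002, with adjusted p = 0.000333 over 10 such tests, 1 of them on the 4 classes together. With overlapping regions counted once, the snRNA share was 2.07% (8 of 386). The heterogeneous class annotated as ncRNA held 162 peaks (38.9%, 9.32-fold over random placement), of which 115 were also at a small RNA gene. The other 47 count below as peaks away from small RNA genes. They include those at the genes for RNase P, RNase MRP and signal recognition particle RNA. Peaks were fewer than at random near piRNA genes (4 against 13.15, adjusted permutation p = 0.004) and pseudogenes (3 against 15.6, adjusted permutation p = 0.00171). No peak lay at the 20 annotated nuclear rRNA genes, none of which had a relaxed region either; how reads that map to several places were treated is unknown, so this 0 does not show that such genes are unbound. Counted by gene, 143 of 612 tRNA genes (23.4%, interval 20.1 to 26.9), 49 of 346 snoRNA genes (14.2%, interval 10.7 to 18.3) and 10 snRNA genes (7.75% of those annotated, interval 3.78 to 13.8) had a peak.

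**Figure D1:**
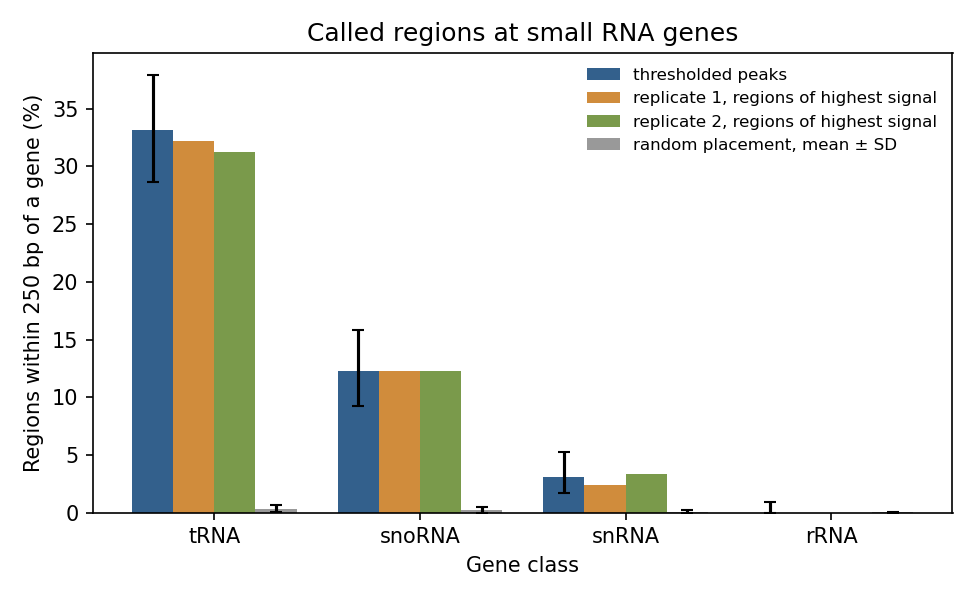
Share of nuclear regions, in percent, with a summit within 250 bp of a gene of each class, for the 416 thresholded peaks (bars with 95% exact intervals), for the 416 regions of highest signal in each replicate, and for random placement (mean ± SD). Peaks at tRNA genes made up 33.2% of the thresholded set, 32.2% in replicate 1 and 31.2% in replicate 2, against 0.352% for random positions.

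The strongest tRNA peak had a signal of 426.3 and lay in C04A11.t1, a leucine tRNA gene (X, 13665555 to 13665673). The alanine tRNA genes F15G9.t1 (X, 9743589 to 9743660) and F15G9.t2 (X, 9743747 to 9743818) were both within 250 bp of a single summit with a signal of 327.9. The cysteine tRNA gene C37A2.t1 (I, 6781803 to 6781874) had 313.9. Shares by amino acid ran from 10.0% of 20 histidine genes to 46.2% of 13 cysteine genes, apart from the single selenocysteine gene, which had no peak. No amino acid differed from the rest after adjustment over 21 classes (smallest adjusted p = 0.695, Fisher's exact test).

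The strongest nuclear peak, with a signal of 688.3 (417.9 in replicate 1 and 265.9 in replicate 2), had its summit at position 12303648 on V. It lay inside the snoRNA gene C51F7.4 (V, 12303599 to 12303693), within an intron of frm-7, and next to C51F7.3. Further strong snoRNA peaks were at W03C9.9 on II with 597.6 and T03F7.8 on V with 464.3. Among the 25 nuclear peaks of highest signal, 13 were at snoRNA genes, 4 at tRNA genes and 1 at an snRNA gene. The median signal was 157.6 at small RNA genes and 118.7 at the 215 other peaks, a difference of 0.41 on the log2 scale (permutation test, p = 1e-05, the smallest 100000 permutations can give).

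Summits took different positions in the 2 main classes. At tRNA genes, 86 of 138 summits (62.3%, interval 53.7 to 70.4) were inside the gene, with a median of 37.5 bp downstream of its 5' end. At snoRNA genes, 42 of 51 summits (82.4%, interval 69.1 to 91.6) were upstream of the 5' end, against 19.6% at tRNA genes (Fisher's exact test, two-sided, odds ratio 19.2, p = 2.59e-15).

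**Figure D2:**
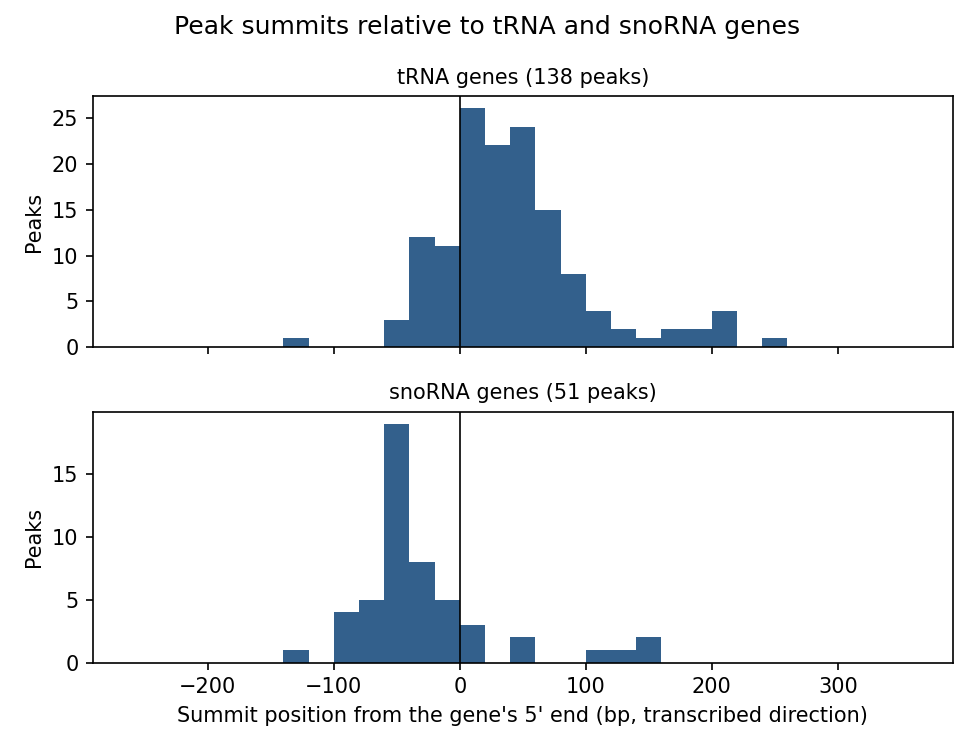
Histograms of summit position relative to the 5' end of the nearest tRNA gene (138 peaks) or snoRNA gene (51 peaks), in bp along the direction of transcription; the vertical line marks the 5' end. Most tRNA summits fall within the gene, whose median length is 73 bp, and 42 of 51 snoRNA summits fall upstream.

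The second question was how peaks related to protein-coding genes. A summit lay within 500 bp of a protein-coding start for 167 of 416 peaks (40.1%, interval 35.4 to 45.0), against 18.3% ± 1.91 for random placement (permutation p = 0.0002, adjusted p = 0.000533). This excess came from peaks away from small RNA genes. Of those 215 peaks, 130 (60.5%, interval 53.6 to 67.0) were promoter-proximal, against 37 of 201 (18.4%) at small RNA genes (Fisher's exact test, two-sided, p = 7.63e-19). Of the promoter-proximal peaks, 64 of 167 (38.3%, interval 30.9 to 46.2) lay between divergent starts, against 12.4% of 7014 promoter-proximal sub-threshold regions (Fisher's exact test, odds ratio 4.39, adjusted p = 4.81e-16). Regions on either side of a start were counted, and the sets were not matched on lying upstream or inside a gene. A preference for shared promoters was therefore not separated from a position upstream of genes. Few peaks fell in coding exons (20 of 416, 4.81%, against 24.4% ± 2.09 for random positions, permutation p = 0.0002).

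Of the 25 gene lists, 2 were over-represented near peaks and none was under-represented. At an unadjusted exact p under 0.05, 3 lists were over-represented and 0 under-represented. Of the genes with any relaxed region near a start, 207 of 6441 (3.21%) had a peak. Histone genes came first, with 8 of 30 (26.7%, Fisher's exact test, odds ratio 11.4, adjusted p = 7.91e-05). Their 8 genes share 6 summits, so the genes are not independent. The peak between his-67 and his-68 (I, summit 9988895) had a signal of 216.7 and the peak near his-59 and his-60 (IV, summit 7487793) had 192.8. Genes for small-subunit ribosomal proteins followed, with 6 of 23 (26.1%, Fisher's exact test, odds ratio 10.9, adjusted p = 0.000818), among them rps-26 with 163.4, rps-28 with 142.9, rps-19 with 119.7 and rps-20 with 113.6. The rps-26 peak also lies within 250 bp of a small RNA gene. For rps-26, rps-19 and rps-20, the start of another gene lies closer to the summit (64, 214 and 155 bp, against 393, 231 and 242 bp). With the promoter distance set to 250 bp, 2 of 13 small-subunit genes had a peak (15.4%, against 2.95% of other genes, Fisher's exact test, adjusted p = 0.699). With the stricter peak set, 2 of 23 had one (8.70%, against 1.40%, Fisher's exact test, adjusted p = 0.350). For the large subunit, 5 of 37 genes had a peak (13.5%, exact test, adjusted p = 0.0513), among them rpl-3 with 292.8, rpl-20 with 219.6, rpl-35 with 188.8 and rpl-15 with 180.6. This list passed the threshold under 5 alternatives (exact test, adjusted p from 0.00113 to 0.0434), and at 250 bp none of its genes had a peak. The summit counted for rpl-20 also lies closer to the start of another gene (175 against 287 bp).

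The remaining lists did not pass the test. Peaks were found near 4 of 45 chromatin regulators, namely lin-35, the worm retinoblastoma gene, with 153.5, and jmjd-1.2, mrg-1 and cfp-1. They were near 3 of 33 folding genes (hsp-1, with 191.6, cct-8 and dnj-13), 3 of 38 splicing and RNA processing genes (snr-1, with 299.3, sftb-6 and cpf-2), and 3 of 41 cell cycle genes (lin-35, knl-3 and sas-5). Among 41 translation factor and synthetase genes, 2 had a peak (eif-3.C and eef-1A.1), as did 2 of 42 respiratory chain genes (ndua-2, with 243.8, and cox-5B), 2 of 40 epidermal and collagen genes (col-85 and col-71) and 2 of 29 signalling genes (egl-17 and pop-1). A single gene had a peak in the proteasome list (cdc-48.1), the neuronal list (daf-19), the membrane traffic list (sec-15) and the list of other developmental transcription factors (pop-1). The peaks counted for col-85, sec-15 and egl-17 lie within 250 bp of a small RNA gene. Some summits, among them those counted for snr-1, lin-35 and ndua-2, lie closer to the start of another gene.

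No peak was found near any of the 80 nuclear hormone receptor genes with a relaxed region (a count of 0 allows up to 3.75%), 31 homeobox genes (9.68%), 33 cytoskeletal genes (9.09%) or 22 Argonaute and small RNA pathway genes (13.6%). The same held for 18 vacuolar ATPase and lysosome genes, 16 maternal and germline genes, 15 early zygotic lineage genes, 12 muscle genes, 7 telomere genes and 6 intestine genes. For each of these lists, the limit that a count of 0 allows lies above the share of other genes with a peak.

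Away from small RNA genes, the strongest peak lay between genes on I (summit 933518, signal 670.9), 4965 bp from the nearest protein-coding start. The peak on IV with summit 14034070 and a signal of 542.7 overlapped the microRNA gene mir-52. Strong peaks with a protein-coding start within 1000 bp were at K12H4.5 (III, summit 8043968, 488.4), at ftt-2, a 14-3-3 gene (X, summit 11605936, 486.8), and at sre-23 (I, summit 8259562, 298.1 in replicate 1 and 197.7 in replicate 2). The ftt-2 summit lies 517 bp from that start and inside the gene F52D10.7, annotated as ncRNA. The sre-23 peak is also the peak at the snoRNA gene ZK265.10.

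Chromosomal distribution was examined next. The X held 92 of 416 peaks (22.1%, interval 18.2 to 26.4), more than its 17.7% of sequence (exact binomial, p = 0.0205, adjusted p = 0.0328). The direction differed between the classes of peak. At small RNA genes, 69 of 201 peaks (34.3%, interval 27.8 to 41.3) were on the X, and among the others 23 of 215 (10.7%, interval 6.90 to 15.6), a difference with odds ratio 4.36 (Fisher's exact test, two-sided, p = 7.28e-09). The X carries 276 of the 612 tRNA genes (45.1%). On the autosomes, 131 of 324 peaks (40.4%, interval 35 to 46) were in the central 33.3% (exact binomial, p = 0.00792, adjusted p = 0.0158). That call was lost with either replicate alone (exact binomial p = 0.0765 without replicate 1 and 0.0576 without replicate 2), and among peaks away from small RNA genes the share was 32.8%.

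**Figure D3:**
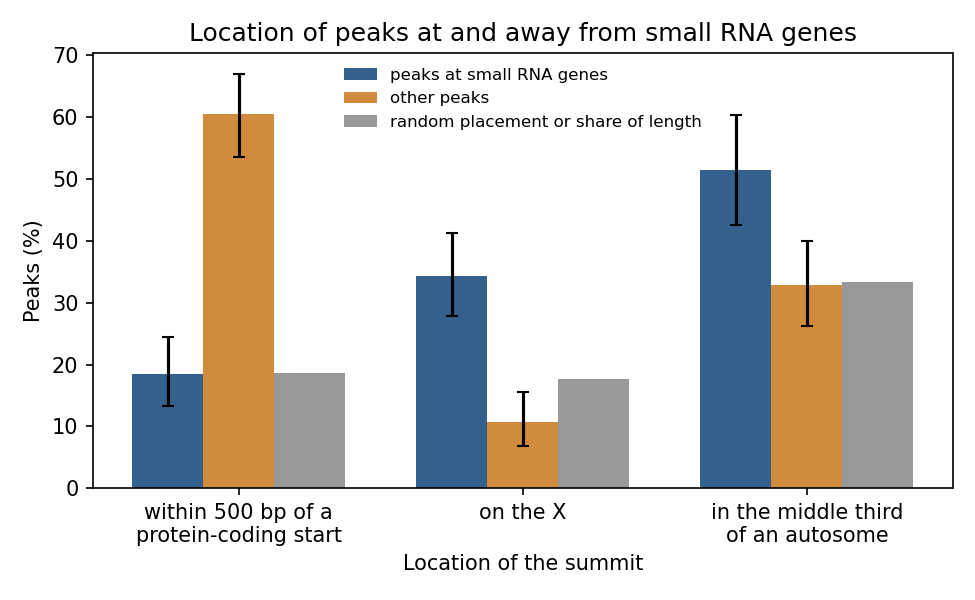
Share of peaks, in percent with 95% exact intervals, near protein-coding starts, on the X and in the central part of the autosomes, for the 201 peaks at small RNA genes and the 215 others; grey bars give the background for the other peaks (random placement for starts, share of length otherwise). Promoter shares are 18.4% and 60.5%, and X shares 34.3% and 10.7%.

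Because human HMBOX1 binds telomeric DNA, chromosome ends and telomere repeats were tested. A single peak lay within 50 kb of a chromosome end (0.240%, interval 0.00609 to 1.33), where the share of sequence is 0.598% (exact binomial, p = 0.528). No peak window held the double repeat TTAGGCTTAGGC (0 of 416, which allows up to 0.721%), against 0.382% of 29307 sub-threshold windows (Fisher's exact test, two-sided, p = 0.413). The TAGTTA word, the core of the human HMBOX1 motif, was in 7 of 416 peak windows (1.68%, interval 0.679 to 3.44) and 2.48% of matched windows (Fisher's exact test, p = 0.400). A difference was not detectable in these 3 tests. How reads that map to several places were treated is unknown, so repeats and chromosome ends may be under-represented in the lists. Backgrounds of 0.598% and 0.382% also leave too few peaks for a lower share to be detected. The first 2 tests therefore do not show that telomeric DNA is unbound.

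The 6-mer screen gave 107 words more frequent in peaks and 40 less frequent among all canonical words. GC content was matched only by decile, and the screen was not tried on simulated sets as GC-rich as the peaks. The number of words called may therefore partly reflect GC content. The first word was GTTCGA, found in 97 of 416 peaks (23.3%) and 4.93% of matched regions (Fisher's exact test, odds ratio 5.86, adjusted p = 9.05e-29). It belongs to the B box, the internal promoter element of tRNA genes, and was in 69 of the 138 peaks at tRNA genes (interval 41.4% to 58.6%). It was also in 13 of 51 peaks at snoRNA genes (25.5%, interval 14.3 to 39.6) and in 6.98% of peaks away from small RNA genes. AGTGGT, part of the tRNA A box, was in 17.5% of peaks and 5.23% of matched regions (exact test, adjusted p = 3.16e-14), and in 25.5% of peaks at snoRNA genes. With peaks at small RNA genes left out, 25 words were more frequent and none less frequent (75 were less frequent at an unadjusted exact p under 0.05). The first was TTGCAA, in 39 of 215 peaks (18.1%) and 4.56% of matched regions (exact test, odds ratio 4.64, adjusted p = 2.18e-08). Over all peaks, the call for TTGCAA was lost in the stricter set. There, 7.69% of 208 peaks and 4.18% of matched regions held it (exact test, adjusted p = 0.266). In that set, 61.5% of peaks lay at small RNA genes, against 48.3% of all 416 peaks. The word was in only 5.80% of peaks at tRNA genes and 1.96% at snoRNA genes, so composition and signal changed together.

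The replicates were compared on their regions of highest signal. Of the top 416 nuclear regions of replicate 1, 286 (68.8%, interval 64.1 to 73.2) overlapped the top 416 of replicate 2, against 0.980% ± 0.485 for regions drawn at random from the same lists. Both lists were called against the same control, which the random draws do not model, so part of the overlap may come from that control. All 416 peaks had a region in each replicate's relaxed list. Across peaks, which are not independent replicates and had been selected for reproducibility, the signal values gave Pearson r = 0.872 and Spearman rho = 0.696 (permutation p = 1e-05 for each). By class, Spearman rho was 0.803 for the 201 peaks at small RNA genes and 0.503 for the 215 others. Over all 11879 relaxed regions found in both replicates, Spearman rho was 0.334 (permutation p = 1e-05).

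**Figure D4:**
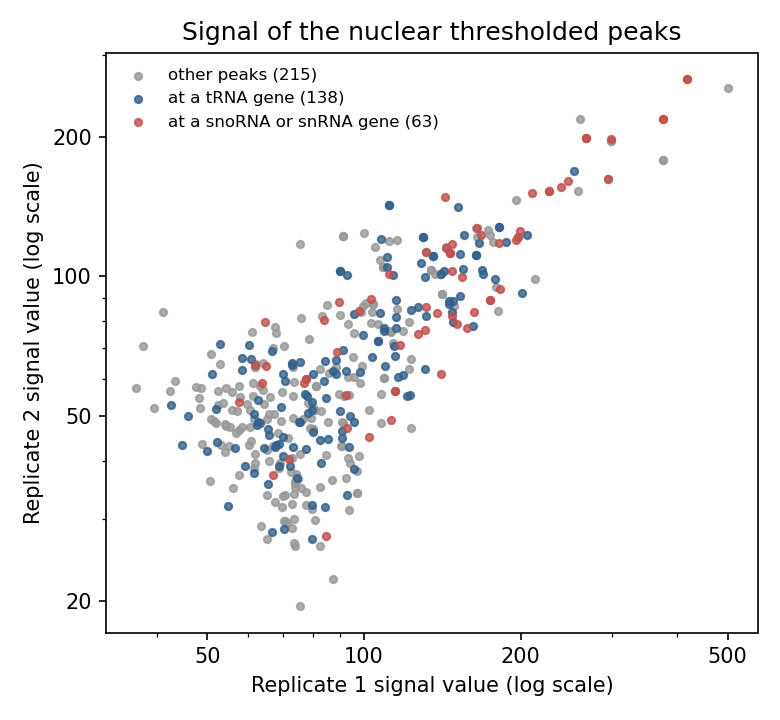
Signal value of each of the 416 nuclear peaks in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), coloured by whether the peak lies at a tRNA gene (138), at a snoRNA or snRNA gene (63) or elsewhere (215). Spearman rho over all peaks is 0.696.

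At the tagged gene itself, no peak was found. The peak nearest to the start of hmbx-1 (I, 989671 to 992178) was 56153 bp away. The 40 kb window around it held 2 relaxed regions in replicate 1 and 1 in replicate 2, percentiles 2.76 and 1.36 among 2503 windows whose medians were 10 and 8. In the pooled relaxed list it held 3, percentile 4.75, but with windows of 80 kb the pooled percentile was 54.2, so a low count holds only close to the gene. Around unc-119 (III, 10902641 to 10908935), the window held 13 relaxed regions in each replicate, percentiles 75.1 and 81.3, and no peak.

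The lists made on the 2 assemblies were nearly equal in size. The thresholded list held 436 regions on ce10 and 437 on ce11, with 90 and 92 on the X and 21 mitochondrial regions in each. Relaxed regions numbered 25206 and 25401 in replicate 1, and 22349 and 22915 in replicate 2.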

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

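The test in this part was chosen after the result was seen. It first used the thresholded list alone, which passed its limit, and was extended to each replicate list when their coverage was already known. Outside the nuclear comparisons, 21 thresholded regions lay on the mitochondrial genome, a signal in data that no comparison of the report uses. The highest signal value there was 3581, against 688.3 among nuclear peaks. The nearest gene starts included those of COX3 and ND6. The 21 summits share 4 distinct regions that cover 12797 of 13794 bp. Called regions thus span 92.8% of the mitochondrial genome in the thresholded list, 69.99% in the relaxed list of replicate 1 and 82.8% in that of replicate 2. For a difference in mitochondrial DNA content between the immunoprecipitated sample and its control, the limit set was coverage over 80% in each list. Replicate 1 did not reach it. The limit was a chosen cutoff, so missing it does not decide on DNA content. Signal at the 21 summits ran from 126.3 to 3581, so the enrichment was not even. Whether DNA content or local enrichment made these regions cannot be told apart, since the control was not analysed here, and no biological explanation was tested.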

How the results depend on the processing

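Of 83 alternative values for the results that answer a comparison, 62 were kept, 12 moved, 2 weakened and 7 changed direction. Tested values were kept if direction and side of the threshold held, and the others if they stayed within a spread or a set fold of the main value. The fold was used for counts of words, lists and regions, so that 152 words, against 107 as designed, counted as kept. The pooled relaxed list is left out of these counts because its top 416 regions are the 416 peaks. The alternatives without peaks at small RNA genes, with overlapping regions counted once, with any transcript start, with each replicate alone at hmbx-1, with sub-threshold regions as background for the RNA gene share and with the ce10 lists for the build comparison were chosen after seeing the data. The RNA gene share, the promoter share and the divergent promoter share kept direction and call under each alternative run for them. Without peaks at small RNA genes, the X share reversed to 10.7%, the autosome centre share went to 32.8%, just under 33.3%; these follow from which peaks were removed. The 6-mer screen then gave 25 words, but with 215 peaks tested, so composition and number changed together. The stricter peak set gave 60 words, with fewer peaks tested, and the flanks of the same peaks, which are not matched on GC, gave 304. With each replicate alone, the autosome centre share was 38.1% to 38.4% and lost its call, the TAGTTA share was 2.40% to 3.12%, above its background in replicate 2 alone, and the telomere-proximal share was 0.481% to 0.721%, above its background in replicate 1 alone. The telomere-proximal share also changed side at 10 kb (0.240%) and 200 kb (2.40%), and the telomere repeat share with 1 copy (7.45%); none of these passed the threshold before or after, and the cause was not tested. The number of lists called was 1 at 250 bp and 4 with all annotated genes as background, and the large-subunit ribosomal list, not called as designed, went to 0% at 250 bp but passed under 5 alternatives (each replicate alone, the stricter set, without peaks at small RNA genes, all annotated genes); the cause was not tested. The replicate overlap was 58.2% for summits within 100 bp, 79.0% for the top 100 and 44.9% for 4 times as many regions. The hmbx-1 percentile was 4.75 in the pooled list, 2.28 for 20 kb, 54.2 for 80 kb and 1.36 to 2.76 with each replicate alone, so a low rank holds only close to the gene; the cause was not tested. No paired analysis was possible because there is 1 group. The rank correlation was 0.334 over all relaxed regions found in both replicates. Replicate overlap and correlation need both replicates, so neither was left out there. Read depth is unknown, which limits every zero count.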

Other observations

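Of the tests in this part, that on single-copy tRNA genes was set before its result was seen; those on GC content, microRNA genes and the X, and the use of the planned test on ribosomal protein genes to weigh an explanation, were chosen after. Some genes within the RNA classes of the report, and microRNA genes, are described here, chosen after their values were seen. The RNase P RNA gene rpr-1 (I, 13463955 to 13464207) had a peak with a signal of 227.8 and the RNase MRP RNA gene mrpr-1 (II, 7200233 to 7200418) one with 174.5. Of 5 genes for the signal recognition particle RNA, 4 had a peak, from 105.9 at srpr-2.1 to 191.9 at srpr-2.2, and srpr-3 had only a relaxed region. Among genes for spliced leader RNAs, annotated as snRNA genes and so counted in that class, 5 of 18 SL2 genes had a peak within 250 bp (sls-2.4 with 373.5 and sls-2.1 with 261.3 were the highest). Of these, sls-2.9 was counted through a summit closer to a lysine tRNA gene, 29 bp from it. The gene sls-2.3 was counted through a summit 216 bp away, in a region that overlaps the sls-2.2 peak. None of 12 SL1 genes had a peak or a relaxed region, which may reflect the unknown treatment of reads that map to several places. MicroRNA genes had 7 peaks within 250 bp, where random placement gave 0.605 (permutation of positions, adjusted p = 0.000333); the 416 regions of highest signal gave 4 in replicate 1 and 9 in replicate 2.

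On tRNA genes, 75 of 276 on the X (27.2%) and 68 of 336 on the autosomes (20.2%) had a peak (Fisher's exact test, two-sided, p = 0.0446, not adjusted). Some of these genes share a summit, such as F15G9.t1 and F15G9.t2 on the X, so the genes are not independent. Peak windows had a mean GC content of 46.7% ± 9.29 (SD over 416 peaks), against 34.6% ± 9.18 in sub-threshold windows.

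The peaks at small RNA genes were weighed against 3 technical explanations. Reads shared between identical gene copies could have made them. Of 143 tRNA genes whose sequence occurs once, 16.08% had a peak (interval 10.5 to 23.1), above the 5% set as the limit. Genes with more copies had 25.6% (Fisher's exact test, p = 0.0180), so sharing may add to part of the pattern. Single copies were defined by the full sequence of annotated tRNA genes, so near-identical copies were not set apart. A gene also counted through any summit within 250 bp, which neighbouring genes can share. Read sharing is therefore not excluded and stays open. For GC content, 3.17% of 4074 sub-threshold regions matched on GC and promoter class lay at small RNA genes (interval 2.65 to 3.75). Sub-threshold regions leave out by definition every region that overlaps a peak, and only 1.43% of all of them lay at such genes. A low share was therefore set in advance, so this comparison cannot decide on GC content, which stays open. ChIP signal that arises at highly transcribed genes whatever the tagged protein stays open, because the small-subunit ribosomal protein list was over-represented too (Fisher's exact test, adjusted p = 0.000818). That call was lost at a distance of 250 bp (15.4% of 13 genes, against 2.95% of others) and in the stricter peak set (8.70% of 23, against 1.40%). Some of the summits counted for this list also lie closer to the start of another gene. The RNase P, RNase MRP and signal recognition particle genes were also compared with other ncRNA genes (6 of 7 had a peak, against 2.22%), but they were picked after their peaks were seen, so no test is drawn from them. Without an untagged strain, these data cannot tell a biological explanation from the technical ones left open.

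The X share of the peaks may follow from the location of tRNA genes. Without peaks at small RNA genes it was 10.7%, below the 17.7% of sequence (exact binomial, p = 0.00552). The peaks removed were 34.3% on the X, so the share had to fall. The excess thus lay among peaks at small RNA genes, and 45.1% of tRNA genes lie on the X. Their location alone was not shown to account for it. On the X, tRNA genes also had a peak more often (27.2% against 20.2%, Fisher's exact test, p = 0.0446, not adjusted). Some of them share a summit, so the genes are not independent and that difference is uncertain. Why the remaining peaks are fewer on the X was not tested, and no biological explanation was tested.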
